A study of Hevea brasiliensis with 18 samples.

How the data were processed

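Gene expression was measured by RNA sequencing in detached mature leaves of the rubber tree Hevea brasiliensis, clone GT1, which the labels describe as susceptible to Pestalotiopsis. Leaves received either a mycelial plug of the fungus Pestalotiopsis microspora or a plug of agar medium as a mock treatment, and tissue around the inoculation sites was taken on day 2, 4 or 6 after the treatment (days post inoculation, dpi). Each of the 6 groups has 3 libraries, 18 in all. Per the labels' protocols, inoculated leaves were punctured on the upper surface, whereas for the control the lower epidermis was abraded, so the wounding as described is not identical in the 2 treatments. The labels also say that leaf samples were pooled per treatment before RNA was isolated with a CTAB buffer. Nothing in the labels says that the 3 libraries of a group come from separate plants, so p-values measure the spread between these libraries, which may be technical.

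Per the labels' protocols, mRNA was enriched with oligo dT beads and the second cDNA strand was made with dUTP, a chemistry that marks strand. Per the submitters' processing notes, STAR 2.7.11a and featureCounts 2.0.6 were used. The genome build, the annotation, the strand setting of the counting and any filter are not given in the sources used here. The deposited values are whole-number counts per gene ID and library, without normalization by the authors, and their sums differ between libraries. Because the strand setting is unknown, IDs that overlap another ID on the opposite strand are uncertain, as are IDs that share reads with a near-identical copy.

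The deposited count table has 84443 IDs, of which 43549 have 0 counts in every library. The IDs carry no gene names or product descriptions. None of them was found among the locus tags, synonyms and symbols of the RefSeq gene table used here (assembly ASM3005281v1, 50196 rows, 0 matches). The gene lists fixed before the data were examined (defence proteins, hormone pathways, transcription factor families, photosynthesis and markers of leaf cell types) could therefore not be applied, and the results below are given for groups of IDs defined by their response. With no names, the rule for single IDs allowed at most 2 that rose and 2 that fell. They were taken from IDs past the threshold on all 3 days, with a mean of at least 10 CPM in the higher group and CPM values that do not overlap between mock and inoculated libraries, ranked by the smallest of their 3 absolute log2 fold changes. Ranking over the 3 days together was chosen after the data were seen. Hb_018202_060 was singled out after its values were seen.

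Counts were analysed in R 4.3.3 with edgeR 4.0.16. IDs passing filterByExpr at its default settings were tested (28474), library sizes were scaled by TMM, and 1 model with a mean for each of the 6 groups was fitted over all 18 libraries with robust dispersion and quasi-likelihood estimates. Contrasts were tested with glmQLFTest, two-sided, and adjusted by the Benjamini-Hochberg method. An ID was called at an adjusted p under 0.05. The contrasts were inoculated against mock on each day, the difference of that effect between each pair of days, and mock leaves at 4 and at 6 dpi against mock leaves at 2 dpi. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of the F statistic. CPM values are TMM-scaled, and log2 CPM used a prior count of 2. The common biological coefficient of variation was 23.4%. A fold against a group at 0 was computed against a floor of 3 counts over that group. Measures of library make-up were compared by an exact permutation test within days, two-sided, over all 8000 arrangements, for which the smallest possible p is 0.00025. Intervals and floors cover counting error only, at a confidence level of 95%.

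Libraries held 17568610 to 21279385 counts. After TMM scaling, 3 counts corresponded to 0.122 to 0.147 CPM in mock and 0.139 to 0.223 CPM in inoculated libraries. No pair of replicates differed by as little as sampling noise: the chi-square per degree of freedom ran from 2.81 to 171 over the 18 pairs within groups. The edgeR procedure was tested on simulated data with 27871 tested IDs and known changes, drawn with the fitted dispersions. Only 196, 197 and 198 IDs were changed at 2, 4 and 6 dpi, a far smaller share than was called in the real data. The rates found hold for that setting and need not hold for the real data. For inoculated against mock, the procedure found 27.3%, 33.7% and 37.8% of the 2-fold changes and 78.4%, 83.8% and 82% of the 4-fold changes at 2, 4 and 6 dpi, and 4.63%, 1.69% and 4.8% of its calls were false. For the differences between days, it found 8.72% (2 and 4 dpi), 13.8% (4 and 6 dpi) and 12.7% (2 and 6 dpi) of the 2-fold changes and 64.4%, 66.3% and 58.4% of the 4-fold changes.

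The alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), DESeq2 size factors and upper-quartile scaling in place of TMM, no filter and a filter of at least 5 CPM in 3 libraries, fits on only the groups compared, an adjusted p under 0.01, a test against a 2-fold change (glmTreat), the replicate number as a block, and leaving out each library in turn. Leaving out 6 dpi mock libraries 1 and 3 together, other count limits for the sets near 0, other scalings and left-out libraries for the groups called on all 3 days, and every alternative for opposite calls and for changes shared by mock and inoculated leaves were added after the data were seen.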

Results

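The data comprise counts per gene ID for mock-treated and Pestalotiopsis microspora-inoculated leaves of rubber clone GT1 at 2, 4 and 6 dpi, with 3 libraries in each of the 6 groups. Total counts per library ran from 17568610 to 21279385 and did not differ detectably between inoculated and mock libraries (exact permutation test within days, two-sided, p = 0.981). The series title names phytohormone responses as its topic. The files pair no names with the IDs, so the comparisons are described by groups of IDs that responded alike.

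Inoculated and mock libraries separated along the first principal component of log2 CPM, which held 52.3% of the variance. On this axis the 9 mock libraries lay between -139 and -65.7, the inoculated 2 dpi libraries between 3.23 and 15.8, and the inoculated 4 and 6 dpi libraries between 78.5 and 169. The second component held 19.1% and separated the inoculated leaves by day. Within the inoculated 6 dpi group, replicate 3 lay at 78.5 on the first component against 144 and 169 for the other libraries.

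**Figure D1:**
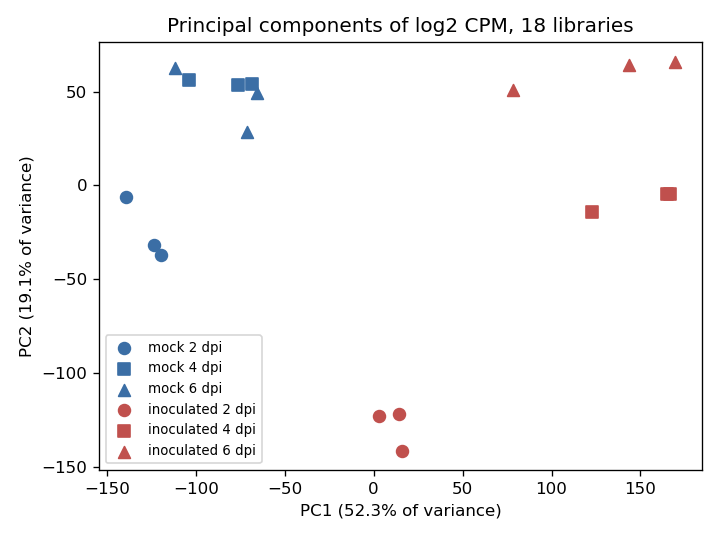
Principal components 1 (x axis, 52.3% of variance) and 2 (y axis, 19.1%) of TMM-scaled log2 CPM, in units of the component scores. Each point is 1 of 18 libraries, coloured by treatment and shaped by day, and every inoculated library lies to the right of every mock library.

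The first comparison asked which transcripts differed between inoculated and mock leaves on each day. At 2 dpi, 3926 IDs were higher and 4743 lower in inoculated leaves, together 30.4% of the 28474 IDs tested. At 4 dpi, 7974 were higher and 8855 lower (59.1%). At 6 dpi, 6549 were higher and 7362 lower (48.9%). The median log2 fold change of the higher IDs was 1.07, 1.13 and 1.05 at 2, 4 and 6 dpi, and that of the lower IDs was -1.54, -1.47 and -1.33. IDs at 0 in a whole group made up at most 203 of these calls on a day and direction, and setting them at their bound gave medians of 1.07, 1.13 and 1.05 for the higher and -1.54, -1.47 and -1.32 for the lower IDs. When a change of more than 2-fold was itself tested, 1053 higher and 1703 lower IDs were called at 2 dpi, 2802 and 3694 at 4 dpi, and 2107 and 2316 at 6 dpi.

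The calls depended on the fit. With only the 6 libraries of each day, 5386 IDs were higher and 5993 lower at 2 dpi, 8646 and 9163 at 4 dpi, and 3597 and 3490 at 6 dpi. More IDs were then called at 2 than at 6 dpi, the reverse of the main fit. The main fit shared its estimate of spread over all days. Replicate pairs varied more at 6 dpi (chi-square per degree of freedom 40.2 to 171) than at 2 and 4 dpi (2.81 to 30.8). Upper-quartile scaling moved the median log2 fold change of all IDs by -0.166 at 4 dpi, -0.177 at 6 dpi and, for the difference between 2 and 6 dpi, -0.101. At 6 dpi it changed the split to 5075 higher and 9606 lower IDs, so that 34.6% of the called IDs were higher, against 47.1% with TMM.

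**Figure D2:**
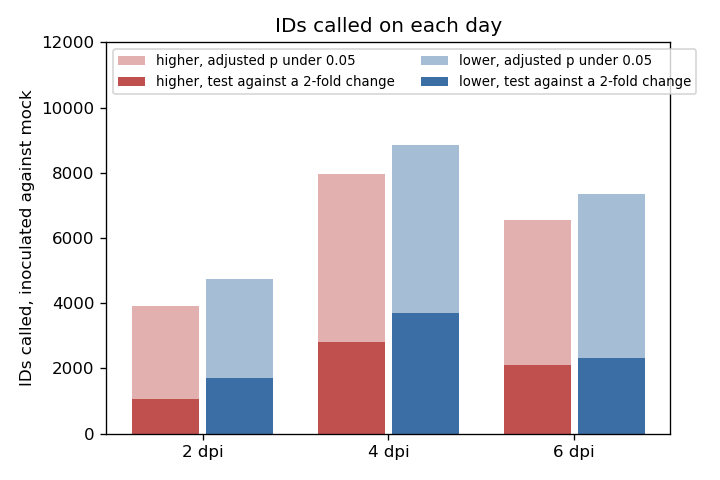
Number of IDs (y axis) called higher or lower in inoculated than mock leaves at each day (x axis). Pale bars show calls at an adjusted p under 0.05 and dark bars those past a test against a 2-fold change, with both directions highest at 4 dpi (7974 higher and 8855 lower).

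A large group of IDs responded in the same direction throughout. Altogether 1897 IDs were higher on all 3 days, where independent lists would share 252.9, and 2230 were lower on all 3 days, against 381.4. With upper-quartile scaling the split was 1410 higher and 2744 lower. The days share no libraries. In the group that was higher throughout, the median log2 fold change was 1.19 at 2 dpi, 1.59 at 4 dpi and 1.53 at 6 dpi. In the group that was lower throughout it was -1.75, -2.40 and -1.82, or -1.75, -2.36 and -1.81 with IDs at 0 set at their bound. The higher group took 14.3% ± 0.460 (SD, n = 3) of all counts in inoculated leaves at 2 dpi, 24.6% ± 2.23 at 4 dpi and 22.5% ± 4.57 at 6 dpi. In mock leaves its share was 6.76% ± 0.351, 7.93% ± 0.825 and 6.9996% ± 1.11 on the same days. The lower group took 7.03% ± 0.564, 6.05% ± 0.659 and 6.39% ± 0.593 of the counts in mock leaves, and 1.84% ± 0.175, 1.10% ± 0.216 and 1.59% ± 0.674 in inoculated leaves. These groups were chosen by their response, so the shares describe their abundance and are not a separate test.

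A set of 191 IDs had at most 10 counts in every mock library and at least 50 in some inoculated library. Of these, 42 were highest at 2 dpi, 40 at 4 dpi and 109 at 6 dpi. Conversely, 262 IDs had at most 10 counts in every inoculated library and at least 50 in some mock library, with 144 highest at 2 dpi, 21 at 4 dpi and 97 at 6 dpi. With a limit of 5 in place of 10 counts, the sets held 105 and 129 IDs, and with at least 100 in place of 50 counts, 103 and 112.

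Among the IDs that rose on all 3 days, Hb_146361_020 had 53.4 ± 5.31 CPM (SD, n = 3) in inoculated leaves at 2 dpi and 0.0982 ± 0.107 in mock leaves, a log2 fold change of 9.02 (SE 0.583, adjusted p = 1.11e-06; 10.13 without mock 2 dpi replicate 3). It had 14.4 ± 2.63 CPM at 4 dpi and 47.3 ± 24.1 CPM at 6 dpi in inoculated leaves and 0 counts in every mock library of those days, which makes it at least 313-fold and at least 1140-fold higher. Hb_033865_020 had 40.9 ± 5.80, 11.3 ± 3.56 and 41.2 ± 18.7 CPM in inoculated leaves at 2, 4 and 6 dpi. In mock leaves it had 0.126 ± 0.111 CPM at 2 dpi and 2 counts in all at 4 dpi, both in replicate 3, for which the count ratio was 367 (95% interval 101.1 to 3030). Its log2 fold change at 4 dpi was 8.27 and ran from 7.71 to 10.85 over 16 alternatives. At 6 dpi it had 0 counts in mock leaves and was at least 993-fold higher. The 2 IDs had similar profiles over the inoculated libraries, although their ratio varied by more than counting noise (chi-square 22.6, df 8), and reads shared between near-identical copies cannot be ruled out for them.

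Among the IDs that fell on all 3 days, Hb_004488_010 had 521 ± 462, 158 ± 90.5 and 997 ± 840 CPM in mock leaves at 2, 4 and 6 dpi, and 4.66 ± 5.78, 0.434 ± 0.604 and 4.40 ± 4.68 CPM in inoculated leaves. Its log2 fold changes were -6.80 (SE 1.27, adjusted p = 0.000729), -8.43 (SE 1.46, adjusted p = 0.000156) and -7.79 (SE 1.33, adjusted p = 0.00021). They varied with single libraries: at 2 dpi -5.77 without mock replicate 1 and -8.49 without inoculated replicate 2, at 4 dpi -10.75 without inoculated replicate 3, and at 6 dpi -6.82 without mock replicate 3 and -9.11 without inoculated replicate 3. Hb_000134_130 had 11.1 ± 1.74, 61.4 ± 26.1 and 35.3 ± 6.20 CPM in mock leaves and 0.142 ± 0.173, 0.1997 ± 0.0499 and 0.271 ± 0.236 CPM in inoculated leaves, with log2 fold changes of -6.19, -8.21 and -6.92 (adjusted p = 1.21e-06, 1.2e-07 and 2.99e-07). Without inoculated 2 dpi replicate 2 the first was -7.65, and without inoculated 6 dpi replicate 3 the last was -7.95.

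Hb_018202_060 became the most counted ID of the inoculated 6 dpi libraries, where it took 5.17%, 4.79% and 1.76% of all counts. Its mean in inoculated leaves was 268 ± 37.1 CPM (SD, n = 3) at 2 dpi, 2064 ± 866 at 4 dpi and 51610 ± 28600 at 6 dpi. In mock leaves it was 37.5 ± 6.83, 15.2 ± 11.6 and 248 ± 381 CPM. The log2 fold change was 2.84 at 2 dpi, which did not pass the test (SE 1.08, adjusted p = 0.0566), 7.08 at 4 dpi (SE 1.31, adjusted p = 0.00028; 7.90 without mock 4 dpi replicate 3) and 7.70 at 6 dpi (SE 1.34, adjusted p = 0.000256). The mock value at 6 dpi rested on replicate 3, with 16331 of the 17724 mock counts of that day; without that library the 6 dpi log2 fold change was 10.80. It was 13.24 without mock 6 dpi libraries 1 and 3.

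**Figure D3:**
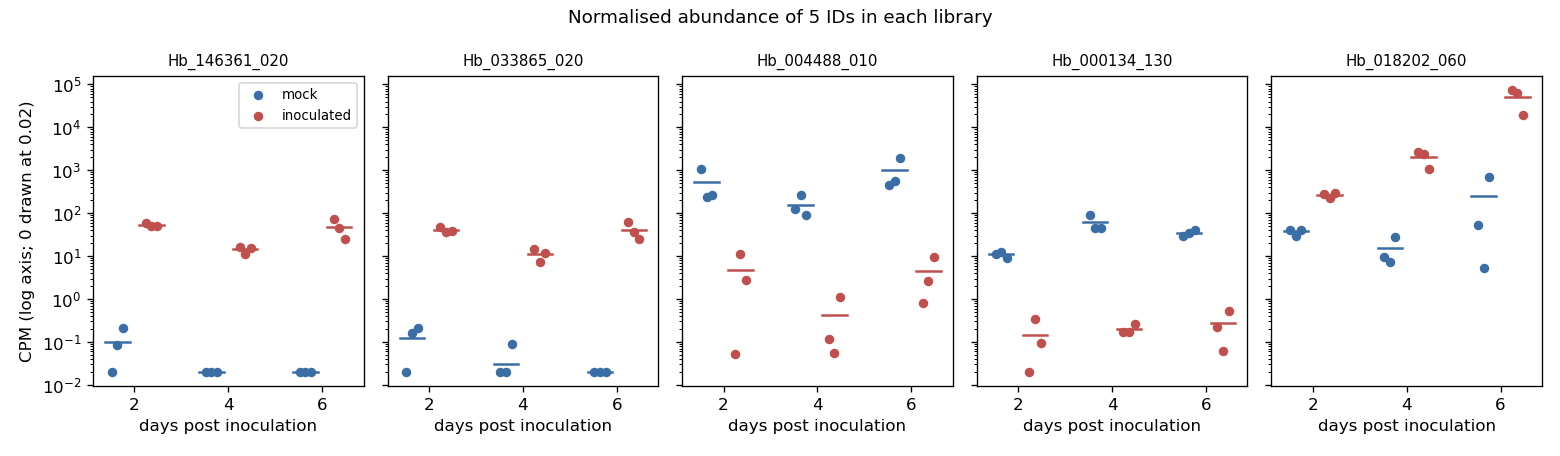
TMM-scaled CPM (y axis, log scale, with 0 drawn at 0.02) of 5 IDs in each library against days post inoculation (x axis). Points are single libraries and horizontal lines are group means (n = 3); the first 2 IDs rose, the next 2 fell, and Hb_018202_060 reached a mean of 51610 CPM in inoculated leaves at 6 dpi.

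The counts of inoculated libraries were spread over fewer IDs. The measures here overlap: where few IDs take more of the counts, fewer counts are left for the rest. A lower number of IDs with a count therefore does not by itself mean fewer expressed genes. Inoculated leaves had 32191 ± 268, 32044 ± 399 and 31434 ± 381 IDs with a count at 2, 4 and 6 dpi (SD, n = 3), and mock leaves 33342 ± 152, 33122 ± 153 and 33736 ± 36.3. All 9 inoculated libraries lay below every mock library of their day (exact permutation test within days, two-sided, p = 0.00025, the smallest it can give; 0.000375 after Benjamini-Hochberg adjustment over 6 measures). The 100 most counted IDs held 13.97% ± 0.876, 17.8% ± 1.60 and 22.04% ± 4.43 of the counts in inoculated leaves and 11.99% ± 0.393, 11.4% ± 0.491 and 11.6% ± 0.398 in mock leaves, again with all 9 inoculated libraries above the mock libraries of their day (exact permutation p = 0.00025, adjusted 0.000375). The number of IDs that together held 50% of the counts fell from 1822 ± 89.9 at 2 dpi to 1223 ± 366 at 6 dpi in inoculated leaves, compared with 2250 ± 93.4 and 2292 ± 38.7 in mock leaves. The difference from mock passed the same exact permutation test over the 3 days (p = 0.00025), while the change from 2 to 6 dpi was not tested.

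**Figure D4:**
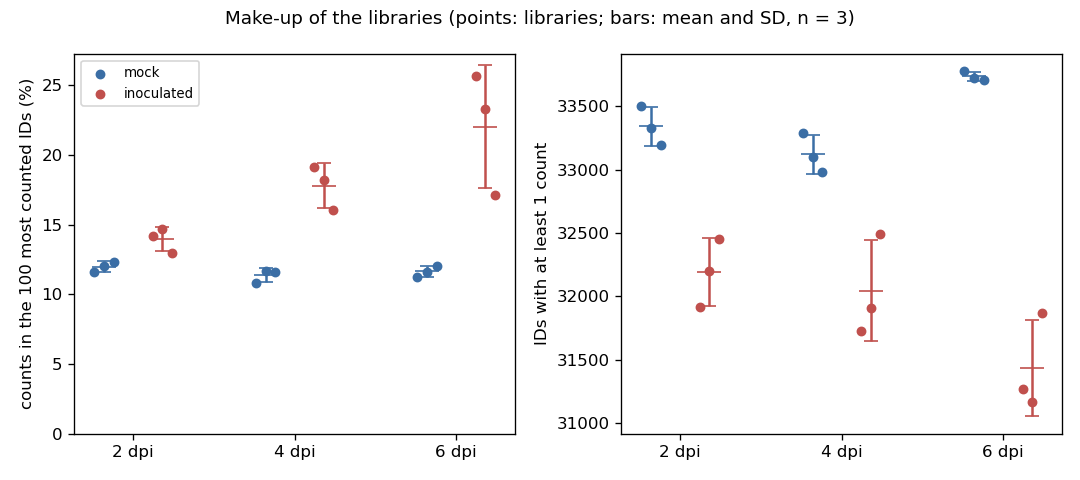
Share of counts in the 100 most counted IDs (left, %) and number of IDs with at least 1 count (right, axis not starting at 0) by day and treatment. Points are libraries and bars show the mean and SD (n = 3); the inoculated libraries lie above the mock libraries of their day on the left (22.04% against 11.6% at 6 dpi) and below them on the right.

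The next comparison asked whether the inoculation effect itself differed between days. It did for 6615 IDs between 2 and 4 dpi, for 6785 between 4 and 6 dpi and for 5111 between 2 and 6 dpi. Within the group that was higher throughout, the effect was larger at 4 than at 2 dpi for 284 IDs and smaller for 60, and from 4 to 6 dpi it was larger for 135 and smaller for 214. Within the group that was lower throughout, the fall was larger at 4 than at 2 dpi for 335 IDs and smaller for 34, and from 4 to 6 dpi it was larger for 85 and smaller for 371. The counts of differing IDs depended on single libraries: 4212 IDs differed between 2 and 4 dpi without inoculated 4 dpi replicate 2, and 8008 between 2 and 6 dpi without inoculated 6 dpi replicate 3. With only the 4 groups compared they were 10774 and 3377, and between 4 and 6 dpi, without mock 6 dpi libraries 1 and 3, 2858.

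Mock leaves also changed with time after detachment. Between 2 and 4 dpi, 2148 IDs rose and 2260 fell in mock leaves, and between 2 and 6 dpi, 1781 rose and 1301 fell. The median log2 fold change of these IDs was 1.18 and -1.49 at 4 dpi, and 1.55 and -1.38 at 6 dpi. Both counts changed when single libraries were left out. Every such omission lowered the 4 dpi total, so having fewer libraries cannot be told apart from the weight of a particular library. The total of 4408 IDs at 4 dpi became 2380 and 2531 without mock 2 dpi replicates 2 and 3, and 2257 and 2426 without mock 4 dpi replicates 2 and 3. The total of 3082 at 6 dpi became 1798 and 1808 without mock 2 dpi replicates 2 and 3. Fits on only the groups compared gave 8863 and 1420.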

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

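Chosen only after results were seen were the tests of carry-over and of a single foreign source of reads, the fit without mock 6 dpi libraries 1 and 3, and the control for the test of fixed ratios.

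The inoculation effect differed between days, by the test of the difference itself, for 6615 IDs (2 and 4 dpi), 6785 (4 and 6 dpi) and 5111 (2 and 6 dpi). Reassigning inoculated and mock labels within each day in 40 drawn arrangements, the real one included, gave as many IDs 2 times for 2 and 4 dpi, where the highest other arrangement gave 7555, a share not under 0.05. That arrangement exchanged all labels of 4 dpi and left 2 of 3 inoculated labels of 2 dpi in place, so it holds the whole 4 dpi effect reversed and part of the 2 dpi effect and is no chance value; the next highest gave 841, and this count does not decide about chance for 2 and 4 dpi. For 4 and 6 dpi (1 of 40, highest other 2071) and for 2 and 6 dpi (1 of 40, highest other 1092) the share was under 0.05. Both of these highest other counts came from 1 arrangement that exchanged all labels of 6 dpi. Arrangements that mix labels put the inoculation effect itself into the spread within groups, and most gave 0 IDs. The shares for these pairs of days therefore decide nothing about chance either. Without inoculated 4 dpi replicate 2 the first count was 4212, without inoculated 6 dpi replicate 3 the last was 8008, and without mock 6 dpi libraries 1 and 3 the second was 2858.

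For the comparisons of 3 libraries against 3, the 10 splits are too few for a share under 0.05. The real split was the 1 with as many calls in each: 8669 IDs at 2 dpi (highest other 0), 16829 at 4 dpi (0) and 13911 at 6 dpi (1195) for inoculated against mock, and 4408 (0) and 3082 (0) for mock leaves at 4 and 6 dpi against 2 dpi. Every other split mixes the groups compared, which puts their difference into the spread within groups. Low counts there therefore decide nothing about chance.

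The difference of the inoculation effect for Hb_018202_060 was 4.24 (log2, adjusted p = 0.0492) between 2 and 4 dpi and 4.86 (adjusted p = 0.0338) between 2 and 6 dpi. These calls were lost in 15 of 22 and 12 of 23 alternatives, over which the adjusted p ran from 0.000408 to 0.178 and from 0.000575 to 0.11. Leaving out a single library ended the call between 2 and 4 dpi for any of the 3 inoculated or 3 mock 2 dpi libraries, for inoculated 4 dpi replicates 1 and 2 and for mock 4 dpi replicates 1 and 2, with differences of 3.90 to 4.38. Between 2 and 6 dpi it ended for any inoculated 2 dpi library, inoculated 6 dpi replicates 1 and 2, mock 2 dpi replicates 1 and 3 and mock 6 dpi replicate 1, with differences of 4.39 to 4.95. Without mock 6 dpi replicate 3 the difference was 7.98, and without mock 6 dpi libraries 1 and 3 it was 10.41.

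Some IDs were called in opposite directions on different days, with a test of the difference passed as well: 382 between 2 and 4 dpi, 790 between 4 and 6 dpi and 395 between 2 and 6 dpi. The counts were the same before the test of the difference, so that test adds no separate support. Of the 790, 588 were higher at 4 and lower at 6 dpi. The first count was 252 without mock 2 dpi replicate 2, and the second 1345 without mock 6 dpi replicate 2. The last was 261 without inoculated 2 dpi replicate 1, 257 and 656 without inoculated 6 dpi replicates 2 and 3, and 595 without mock 6 dpi replicate 2.

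For the 790 IDs, 3 technical explanations were weighed. Without inoculated 6 dpi replicate 3, the weaker library of its group, 640 still passed the 3 tests, which argues against that library as the whole cause. That 100% kept opposite signs adds little. Leaving out the library nearer mock made the 6 dpi effects larger (median absolute log2 fold change 1.21 against 1.15). Under upper-quartile scaling 590 passed; that 100% kept opposite signs there decides nothing, since the smallest absolute log2 fold change, 0.264, exceeded the shifts in the median of all IDs (-0.166 at 4 dpi and -0.177 at 6 dpi). Without mock 6 dpi libraries 1 and 3, which leaned towards the 4 dpi inoculation response (below), 90.38% kept opposite signs. This share counts signs only, whether or not an ID still passed the tests, and is not comparable with the 640 and 590 above. The exact binomial 95% interval, 88.1 to 92.3%, treats the IDs as independent, which they are not. The median absolute log2 fold change at 6 dpi was 0.709 against 1.15 before, so a contribution of these mock libraries stays open. In that fit the single remaining 6 dpi mock library is assumed to vary like the other groups. Scaling, for the IDs that no longer passed under it, and a change of direction in the leaf's response, untested, also stay open.

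Mock 6 dpi libraries 1 and 3 leaned towards the inoculation response. Over all IDs called at 4 dpi, higher and lower together, log2 CPM relative to mock 2 dpi leaves was regressed on the 4 dpi response. Slopes were 0.179 and 0.138, against -0.0427 in replicate 2 and 0.439 ± 0.0274 (SD, n = 3) in inoculated 2 dpi leaves, and were not tested. On the first principal component, libraries 1 and 3 lay at -71.0 and -65.7. Mock 4 dpi replicates 2 and 3 lay near them, at -76.0 and -68.5, and replicate 1 at -104. A shift on that axis was thus not particular to libraries 1 and 3. IDs higher on all 3 days were not clearly raised. They took 6.79% and 8.20% of the counts in libraries 1 and 3, against 6.37 to 7.05% in mock 2 dpi and 6.98 to 8.46% in mock 4 dpi libraries. Carry-over of RNA or reads from inoculated 6 dpi leaves at a fixed share was tested on 50 IDs abundant there and near 0 in the 2 and 4 dpi mock libraries. In mock replicate 3 their median level was 1.72% of the inoculated level, but the lowest upper 95% limit was 0.1389% and 6 IDs had limits under 1/5 of the median (5 to 8 with any single inoculated 6 dpi library as the source), so 1 fixed share is not the whole cause. In replicate 1 the median was 0.6% and the lowest limit 0.09649%, with 1 ID under 1/5 of the median, and carry-over cannot be told apart from a response of these leaves because too few IDs decide. A smaller carry-over alongside a response of the leaf, and a response of mock leaves by themselves, stay open in both.

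For the 191 IDs near 0 in mock leaves, a single foreign source of reads such as the fungus, at 1 constant make-up, would make nearly every ID highest on the same day. The commonest day, 6 dpi, held 57.07% (exact binomial 95% interval 49.7 to 64.2%). The IDs were read in the same libraries and are not independent, so the interval does not cover the spread between libraries. The share argues against 1 such source for the whole set but not for part of it, nor against a source whose make-up changes. Reads shared between near-identical IDs, or pieces of 1 transcript, would give each ID a partner at a fixed ratio. That held for 93.19% of the set, but unrelated rising IDs thinned to the same totals gave 93.7 to 97.9% in 5 draws, so the test is void and shared reads cannot be told apart from separate IDs. Transcription induced by inoculation remains an open explanation.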

How the results depend on the processing

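Added after the data were seen were the fit without mock 6 dpi libraries 1 and 3, the other count limits, the groups called on all 3 days under other scalings or without single libraries, and every alternative for opposite calls and mock drift. No count of calls changed by more than 1.5 times under DESeq2, limma-voom, DESeq2 size factors, upper-quartile scaling or either filter on low counts. Upper-quartile scaling did move the balance towards lower IDs: 3281 higher and 5252 lower at 2 dpi, 6451 and 10284 at 4 dpi, 5075 and 9606 at 6 dpi, and 1410 and 2744 on all 3 days. The 4 IDs named by the rule kept direction and call in every alternative run for them. They had been picked from these data for large fold changes on all 3 days, so this says little about other IDs. With limma-voom, Hb_004488_010 had log2 fold changes of -8.14 at 2 dpi and -9.17 at 4 dpi. Hb_018202_060 then had 9.58 at 6 dpi, against 7.70 in the main fit. Its log2 difference between 2 and 6 dpi was 6.74 against 4.86.

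Replicate numbers did not pair the libraries: 1 of 9 same-numbered pairs correlated over 0.1 (r from -0.321 to 0.12), and 3 of 18 libraries correlated best with their own number. With a replicate block 3747 IDs were higher and 4613 lower at 2 dpi, and no count of calls moved by more than 1.5 times.

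At an adjusted p under 0.01, the calls were 2413 higher and 3098 lower at 2 dpi and 4795 lower at 6 dpi, and the effect differed for 2670 (2 and 4 dpi), 3274 (4 and 6 dpi) and 2236 (2 and 6 dpi). Mock leaves then differed for 1954 (4 dpi) and 1446 (6 dpi), and 1021 were higher and 1243 lower on all 3 days. Against a 2-fold change, they were 1053 higher and 1703 lower (2 dpi), 2802 and 3694 (4 dpi), 2107 and 2316 (6 dpi), with 1051, 1703 and 1189 for the differences between 2 and 4, 4 and 6, and 2 and 6 dpi, and 746 and 623 for mock leaves. Both settings are stricter by construction. With only the groups compared, 5386 were higher and 5993 lower at 2 dpi, and 3597 and 3490 at 6 dpi, so more IDs were called at 2 than at 6 dpi. In these fits the effect differed for 10774 (2 and 4 dpi) and 3377 (2 and 6 dpi), and mock leaves for 8863 (4 dpi) and 1420 (6 dpi). The cause was not tested. Without mock 6 dpi libraries 1 and 3, 2858 differed between 4 and 6 dpi, with fewer libraries and 1 mock library left.

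Leaving out 1 library at a time gave 2257 to 3598 IDs for mock leaves at 4 against 2 dpi, 1798 to 4341 at 6 against 2 dpi, 4212 to 7255 for the difference between 2 and 4 dpi and 3458 to 8008 between 2 and 6 dpi. For Hb_018202_060, whose effects at 4 and 6 dpi did not differ detectably (log2 difference 0.62, adjusted p = 0.8), the sign reversed to -0.20 without mock 4 dpi replicate 3. The difference passed at 3.74 without mock 6 dpi replicate 3, and was 6.18 without mock 6 dpi libraries 1 and 3. Replicate 3 held 626 of the 994 mock counts at 4 dpi and 16331 of the 17724 at 6 dpi. Why these libraries were high was not tested. The 2 dpi fold change of Hb_018202_060 passed with DESeq2 and with only the groups compared (adjusted p 1.02e-05 to 0.223 over 16 alternatives). The gene lists were not run, since the files pair no names with the IDs and none was found in the RefSeq gene table used. Depth and TMM scaling together set a floor of 0.122 to 0.223 CPM for 3 counts.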

Other observations

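Of the tests here, that of mock drift and the comparison of IDs further apart in their numbering were chosen after the result was seen.

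Fold changes of the 3 days correlated across the 28474 IDs, which are not independent replicates, with Pearson's r of 0.684 for 2 and 4 dpi, 0.658 for 4 and 6 dpi and 0.614 for 2 and 6 dpi. Altogether 22067 IDs (77.5% of those tested) were called on at least 1 day, and 6407 on none.

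IDs that follow each other in their numbering (the same stem, suffixes next to each other) tended to change in the same direction. Of adjacent pairs with both IDs called, 66% at 2 dpi, 59.7% at 4 dpi and 61.8% at 6 dpi shared a direction, while the highest of 1000 shuffles of the responses over IDs gave 54.3%, 52.2% and 53.3%. For IDs 2, 3, 5 and 10 places apart the share was 59.8%, 57.1%, 53.3% and 50.4% at 2 dpi, 53.4%, 52.2%, 51.7% and 50.8% at 4 dpi, and 55.1%, 55.1%, 50.4% and 51.5% at 6 dpi. Without the 149 pairs that correlated tightly within both treatments it was 65%, 59% and 61%, but this left out only 44, 98 and 76 called pairs, too few to bring the share down to the shuffles, so it decides nothing about 1 transcript annotated as several IDs. A hypothesis is that numbering follows position and that neighbouring genes, such as tandem copies, may share their response; with no annotation used here, the lowest daily share, 59.7%, bears on the pattern and not on positions, and split gene models and overlapping or read-through transcripts stay open.

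Among IDs called in both comparisons, mock leaves changed with time partly in the direction of the inoculation response. Of IDs called both between mock leaves at 6 and 2 dpi and by inoculation at 4 dpi, which share no libraries, 69.76% had the same direction: 1012 were higher in both (498.8 for independent lists) and 471 lower in both (404.6). It was 61.99% and 75.06% without mock 2 dpi replicates 1 and 2, and 59.95% and 79.90% without mock 6 dpi replicates 1 and 2. The value thus rests partly on mock 6 dpi replicate 1, 1 of the libraries with a raised slope on the 4 dpi response. That slope was -0.0427 in mock 6 dpi replicate 2, so by this measure not every mock library leaned this way. It was -0.00314 ± 0.0556 (SD, n = 3) in mock 4 dpi leaves. Those libraries enter the 4 dpi response with a minus sign, which lowers their own slope. Their slope therefore cannot show whether they leaned. In the other pair without shared libraries, mock leaves at 4 against 2 dpi and inoculation at 6 dpi, 78.94% had the same direction, and 61.49% without mock 6 dpi libraries 1 and 3. A candidate explanation is a component shared by ageing or wounding of detached leaves and the response to inoculation, which the design cannot separate from a low response in mock leaves.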
